A study of Mus musculus with 12 samples.

How the data were processed

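Liver RNA of 12 C57BL/6 mice was measured on 12 Affymetrix mouse 3′ expression arrays, with 3 mice of each sex and each somatostatin genotype at 16 weeks of age. About 100 mg of liver and 250 ng of RNA were used per sample, per the labels' protocols. The deposited values are probe set summaries on the log2 scale, made with RMA per the submitters' processing notes, and they were taken without further transformation. The replicates are separate mice, as the design in the series record states, and the 12 columns of values were assigned to groups by their labels, with 0 columns left over. The choices of groups, contrasts, tests, filters, gene lists, named genes and most alternatives were made before the data were examined.

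Of 45101 probe sets, 64 were controls, 34945 named 1 gene, 932 named several and 9160 named none. Gene names came from the array annotation and were looked up in a RefSeq gene table by Entrez identifier, where 99.4% matched and 0 symbols were updated. That table, on the GRCm38.p6 assembly, was also used to order the genes beside Sst. For each of 18193 genes the probe set with the highest mean over all arrays was used. A gene was tested when that probe set exceeded the median of the array on at least 3 arrays, which left 12158 genes. Probe sets that name several genes or none were left out of the gene counts and tested apart. Close relatives within gene families can bind the same probes, so the values of such genes are less certain.

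A group-means model with 4 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 8 residual and 3.72 prior degrees of freedom. There were 5 contrasts: females minus males in wild type, knockout minus wild type in males and in females, females minus males in the knockout, and the interaction, which is the knockout effect in males minus that in females. P-values were adjusted by Benjamini-Hochberg over the 12158 genes within each contrast, with a threshold of 0.05. All p-values of single genes are from limma. The standard errors are those of the moderated fit. Tables were read with data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

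Genes named in the text were the 8 most raised and 8 most lowered per contrast among those past the threshold whose 3 arrays per group did not overlap, up to 4 called members of each list with the largest changes, and 16 genes named in every case. For the interaction no condition on overlap was set. Clock genes, called cell type markers, members of the common response, genes beside Sst, genes still called in the knockout and terminal complement genes named outside this rule were chosen after their values were seen.

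Lists of 19 gene groups and 14 cell type marker groups were fixed from general knowledge: male-biased and female-biased liver genes, major urinary proteins, the growth hormone and IGF axis, the somatostatin system, glucocorticoid handling, lipogenesis, fatty acid oxidation, cholesterol biosynthesis, bile acids, gluconeogenesis, the clock, acute phase, interferon, proliferation, the unfolded protein response, xenobiotic response, and Y- and X-linked genes. For each list the genes past the threshold were counted, over all genes and with adjustment over the list alone. Camera was run for the 30 lists with at least 3 tested genes, with a preset correlation of 0.01 between genes and with an estimated one, and adjusted by Benjamini-Hochberg over the lists of each contrast. Of 150 such tests 41 passed with the preset and 10 with the estimated correlation.

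Sex-biased genes were those past the threshold in wild type with at least a 2-fold difference. Each array was projected on the wild-type difference over these genes, with wild-type arrays placed on an axis built without them, and groups were compared by exact permutation. The overlap between contrasts was set against independent lists of the same sizes and against 100 simulated draws of groups without an effect that share the control arrays. The 40 tested genes nearest to Sst were compared with all others by Fisher's exact test.

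The number of arrays limits the precision. In simulated data with known changes for 50 of 12158 genes at each size, the test of the knockout effect in males recovered 24% of changes of 0.5 log2, 80% of changes of 1 and 100% of changes of 2, with 3 unchanged genes called. The interaction test recovered 2%, 48% and 96%.

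Alternatives covered the filter on dim probe sets, the choice of probe set, normalization, the replicate number as a block, array weights, the prior of limma, a linear model without moderation, a 2-fold minimum, fits to the 6 arrays compared, other axes and windows, and leaving out each array in turn. A clock covariate (the first principal component of the clock list), a 3′ to 5′ covariate (the mean of the Gapdh and beta-actin differences), and leaving out wild-type females 1 and 2 or wild-type males 1 and 2 together were chosen after seeing the data.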

Results

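The series compared the livers of male and female mice with and without somatostatin, a peptide hormone that inhibits the release of growth hormone from the pituitary. In rodents the sex-specific pattern of growth hormone release is known to set many sex differences in the liver, and the series asks how loss of somatostatin alters them. Liver RNA of 12 C57BL/6 mice aged 16 weeks was measured on 12 Affymetrix 3′ expression arrays, 1 per mouse. There were 3 arrays in each of 4 groups: wild-type males, knockout males, wild-type females and knockout females. Values were the deposited RMA values on the log2 scale, and array medians lay between 4.94 and 4.97. The number of arrays limits the precision, and all differences below are log2 differences with the standard error of the limma fit and n = 3 per group. Where the dimmer group of a comparison averaged below the array median, its signal could not be told from background, so the difference is a lower bound without exact rank, and interaction values that use such a level are not exact either. This holds for Cyp2b9, Slc22a26, Sult3a1, Hao2, Rad51b, Cyp3a16, Eci3, Tafa2 and Cd3g in wild-type males, Xist in males, Cyp4a12a, Scara5 and the Y-linked genes in females, Hsd3b5 and Ugt2b38 in knockout females, and Cyp4a12a, Ugt2b38, Scara5 and Ttc7b in knockout males.

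The targeted gene gave no check of the genotype labels. The single probe set of Sst read 5.51 ± 0.17 (SD, n = 3) in wild-type males and 5.43 ± 0.02 in knockout males, and 5.42 ± 0.16 in wild-type females and 5.31 ± 0.03 in knockout females. These levels lay close to the array median in all 4 groups, and where the probe set lies relative to the deleted part is not given in the sources used here. The knockout difference for Sst was −0.08 ± 0.11 in males and −0.12 ± 0.11 in females, neither past the threshold (limma adjusted p = 0.771 and 0.629). The sex labels were borne out on all arrays. Eif2s3y, a Y-linked translation factor gene, read 9.68 ± 0.11 in wild-type and 9.44 ± 0.12 in knockout males against 3.42 ± 0.33 and 3.54 ± 0.27 in the females. Xist, the RNA that silences 1 X chromosome in females, read 12.21 ± 0.18 and 12.17 ± 0.15 in wild-type and knockout females against 4.76 ± 0.15 and 4.45 ± 0.06 in the males.

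Arrays of the same group also differed from one another. The difference between the 3′ and 5′ probe sets of the Gapdh control, which grows as RNA is degraded, was 0.95 and 0.46 in wild-type females 1 and 2 and lay between −0.09 and 0.17 on the other 10 arrays. The corresponding beta-actin difference was 2.59 and 1.92 on those 2 arrays and at most 1.43 elsewhere. Genes of the circadian clock varied widely within groups. Per2 read 8.23 and 8.64 in wild-type males 1 and 2 but 5.63 in wild-type male 3, and between 5.55 and 6.44 in the knockout males. None of the 15 measured clock genes passed in any of the 5 contrasts, and none passed when adjusted over the list alone.

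**Figure D1:**
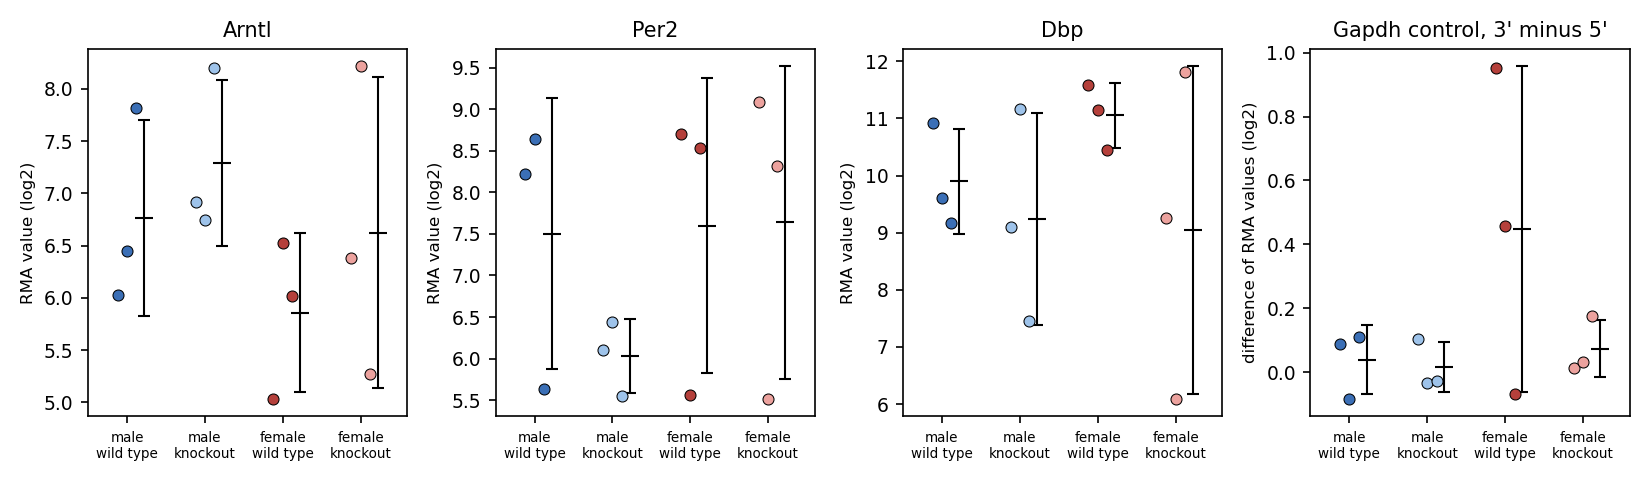
RMA values (log2) of the clock genes Arntl, Per2 and Dbp, and the difference between the 3′ and 5′ probe sets of the Gapdh control (log2), for each of the 12 arrays by group. Points are arrays and bars show the group mean ± SD (n = 3), with Gapdh differences of 0.95 and 0.46 in wild-type females 1 and 2 against at most 0.17 elsewhere.

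In wild-type liver, Xist was higher in females by 7.46 ± 0.13 (limma adjusted p = 4.22e-12). Cyp2b9, a cytochrome P450, was higher in females (7.16 ± 0.26, adjusted p = 1.09e-08), and Cyp2b13, its close relative, was higher by 6.76 ± 0.48. The organic anion transporter Slc22a26 was higher by 7.10 ± 0.12, the sulfotransferases Sult3a1 and Sult2a2 by 7.07 ± 0.34 and 5.62 ± 0.67, the peroxisomal oxidase Hao2 by 5.75 ± 0.24 and Rad51b by 4.64 ± 0.50. The fatty acid hydroxylase Cyp4a12a was lower in females (−7.54 ± 0.43, adjusted p = 8.39e-07). The steroid reductase Hsd3b5 (−6.77 ± 0.68), the glucuronosyltransferase Ugt2b38 (−5.27 ± 0.41), Nat8 (−4.64 ± 0.22), the fatty acid elongase Elovl3 (−4.56 ± 0.66), Scara5 (−4.54 ± 0.60) and Cyp2d9 (−3.50 ± 0.48) were also lower in females.

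Lists of sex-biased liver genes fixed beforehand followed these directions. Of 18 measured male-biased genes, 16 were lower in females and 2 did not pass, and all 18 were lower when adjusted over the list alone. Examples were Cyp7b1, an oxysterol hydroxylase of bile acid synthesis (−3.10 ± 0.12), Slco1a1, an organic anion transporter (−2.58 ± 0.57), and Bcl6, a transcriptional repressor (−2.06 ± 0.41). Of 24 measured female-biased genes, 15 were higher in females and 9 did not pass, with 23 higher when adjusted over the list alone. Camera gave adjusted p = 2.04e-41 and 4.88e-38 for these lists, and adjusted p = 0.0024 for both with an estimated correlation. Of 3 measured major urinary protein genes, Mup10 (−2.88 ± 0.33) and Mup3 (−0.72 ± 0.14) were lower in females. Serpina6, which encodes corticosteroid-binding globulin, differed by 0.89 ± 0.24 and did not pass (adjusted p = 0.0973). Igf1, Ghr and Socs2 did not pass either, with differences of −0.06 ± 0.12, 0.00 ± 0.12 and 0.33 ± 0.25.

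Among the other lists, few members passed in wild type. Of 11 measured interferon response genes, Gbp3 (1.42 ± 0.17) and Ifit2 (1.17 ± 0.23) were higher in females, with 6 higher when adjusted over the list alone. The call of camera for this list was lost with an estimated correlation (adjusted p = 0.217). Of 15 xenobiotic response genes, Cyp2b10 (2.52 ± 0.51) and Nqo1 (0.80 ± 0.16) were higher. Of 16 acute phase genes, Apcs (1.12 ± 0.21) and Itih4 (0.47 ± 0.10) were higher, and of 17 fatty acid oxidation genes, the pantetheinase gene Vnn1 was (1.28 ± 0.28). The camera calls of the last 2 lists were lost with an estimated correlation (adjusted p = 0.372 and 0.380). No member of the lipogenesis (15 measured), cholesterol biosynthesis (16), gluconeogenesis (14) or glucocorticoid (20) lists passed, and 4, 3, 0 and 2 of them were higher when adjusted over the list alone. Camera called the first 3 of these higher in females, and the calls were lost with an estimated correlation (adjusted p = 0.283, 0.325 and 0.217). The bile acid list, in which Cyp7b1 alone passed among 15 genes, likewise had an adjusted p of 0.217 with an estimated correlation. The growth hormone and IGF list held 1 called gene of 20, Bcl6.

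Of the cell type markers in wild type, Cd3g of T cells was higher in females (0.70 ± 0.15) and the other 5 of 6 T and NK cell markers did not pass. Alas2, the erythroid enzyme of heme synthesis and the 1 measured red cell marker, was lower (−2.60 ± 0.14), as was the pancreatic elastase gene Cela1 (−1.29 ± 0.18) while the other 2 measured pancreas markers did not pass. None of the 10 markers of Kupffer cells, the liver macrophages, passed over all genes, nor did the 8 endothelial or 8 stellate cell markers. With adjustment over the list alone 5, 2 and 6 of them were higher. Camera called these 3 lists and the T and NK cell list, and the calls were lost with an estimated correlation (adjusted p = 0.319, 0.217, 0.217 and 0.217). The measured markers of hepatocytes, cholangiocytes, B cells and neutrophils did not pass. The Y-linked list was lower for all 3 measured genes, and Xist and Eif2s3x (0.48 ± 0.10) passed among the 5 of the X-linked list.

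In all, limma called 245 of 12158 genes in wild type, 163 higher and 82 lower in females. With each array shifted to a common median the split was 126 and 105. The count was 135, 119 and 413 without wild-type male 1, 2 or 3 in turn, and 114 with a 3′ to 5′ covariate. Without wild-type females 1 and 2 it was 79 and without wild-type males 1 and 2 it was 63, each with a single array left in that group, which was assumed to vary like the other groups.

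In knockout males, Cyp2b9 rose by 7.69 ± 0.26 (adjusted p = 1.19e-08), Sult2a2 by 7.50 ± 0.67, Sult3a1 by 7.07 ± 0.34, Slc22a26 by 6.99 ± 0.12 and Hao2 by 6.74 ± 0.24. Cyp3a16, another cytochrome P450, rose by 6.93 ± 0.76, Cyp2b13 by 5.00 ± 0.48 and Rad51b by 4.99 ± 0.50. Cyp4a12a fell (−6.77 ± 0.43, adjusted p = 2.58e-06, and −7.42 without knockout male 1, the brightest of the 3 at 6.24). Hsd3b5 (−6.60 ± 0.68), the pseudogene Serpina4-ps1 (−6.54 ± 0.75), Slco1a1 (−6.50 ± 0.57), Ugt2b38 (−5.98 ± 0.41), Cyp2d9 (−4.98 ± 0.48), Nat8 (−4.60 ± 0.22) and Scara5 (−4.37 ± 0.60) fell as well.

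**Figure D2:**
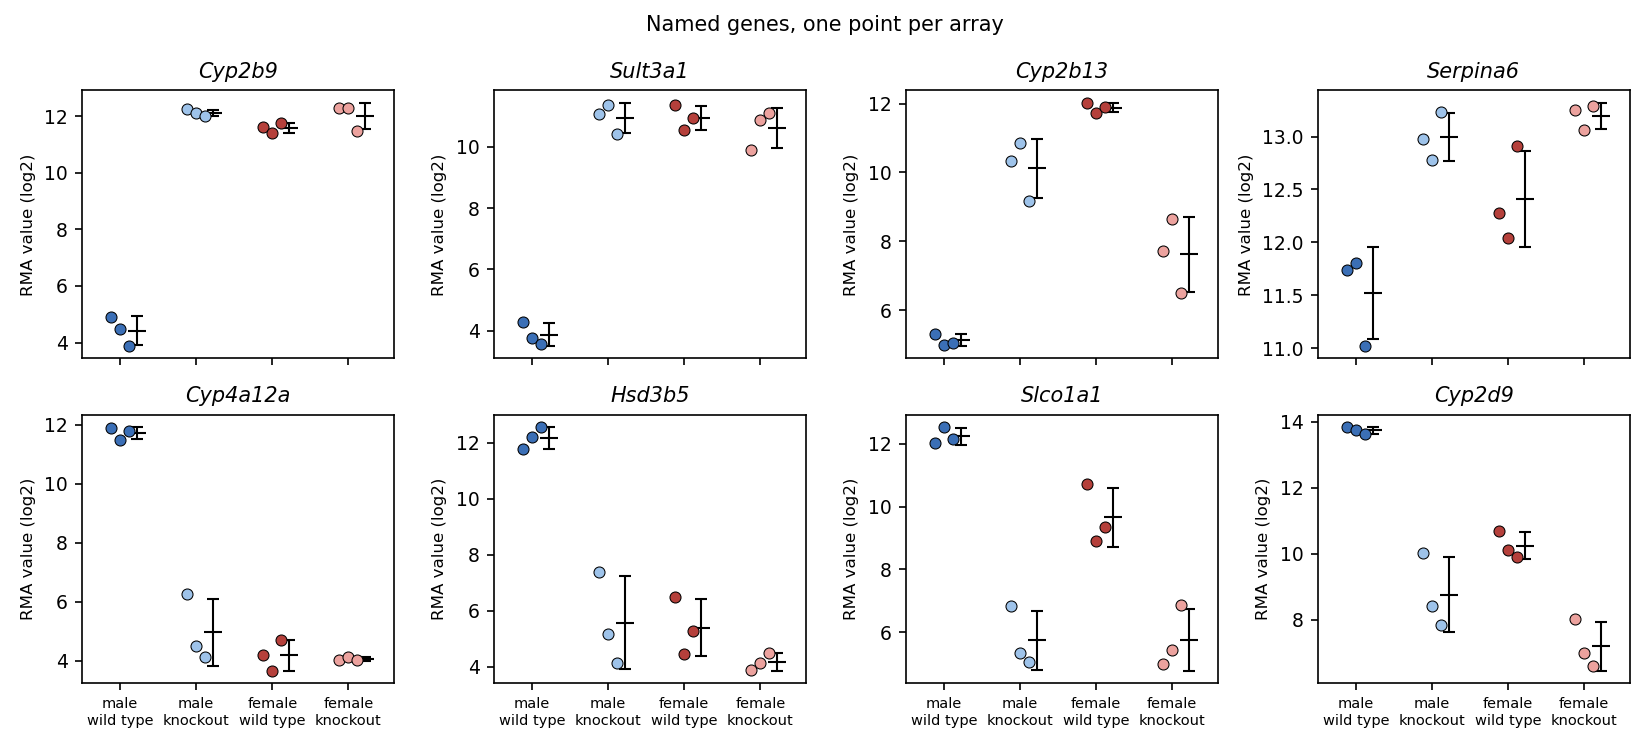
RMA values (log2) of 8 named genes on each of the 12 arrays by group. Points are arrays and bars show the group mean ± SD (n = 3): Cyp2b9 stood at 4.42 ± 0.52 in wild-type males and at 12.12 ± 0.11 in knockout males, and Cyp2b13 at 11.88 ± 0.14 in wild-type and 7.62 ± 1.09 in knockout females.

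Of the 18 measured genes of the fixed male-biased list, 17 fell in knockout males and 1 did not pass, with the same count adjusted over the list alone. Elovl3 (−4.04 ± 0.66), Cyp7b1 (−2.85 ± 0.12) and Bcl6 (−2.44 ± 0.41) were among them. Of the 24 measured genes of the female-biased list, 19 rose and 5 did not pass, with 20 higher adjusted over the list alone. Camera gave adjusted p = 2.78e-38 and 9.74e-39, and p = 0.0049 and 0.0044 after adjustment with an estimated correlation. Mup10 (−1.37 ± 0.33) and Mup3 (−0.78 ± 0.14) fell, and the call of camera for the urinary protein list was lost with an estimated correlation (adjusted p = 0.181).

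Of the 20 measured genes of the growth hormone and IGF list, Igfals rose by 0.74 ± 0.17 and Bcl6 fell, while 18 did not pass. Igf1, the main hepatic target of growth hormone, differed by −0.14 ± 0.12, Ghr by −0.22 ± 0.12 and Socs2 by −0.31 ± 0.25. The probe sets of the transcription factor Cux2 disagreed: the brightest differed by 0.07 and a dimmer one by 3.88. In the glucocorticoid list, Serpina6 rose 2.78-fold (1.48 ± 0.24, adjusted p = 0.0050) and the metallothionein Mt1 by 2.52 ± 0.48, and 18 of 20 genes did not pass. With adjustment over the list alone, 7 genes of that list were higher and 2 lower. None of the 4 measured genes of the somatostatin system passed in any of the 5 contrasts.

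Other lists moved in part. Of 17 fatty acid oxidation genes, Cyp4a14 (1.69 ± 0.42), Vnn1 (1.47 ± 0.28) and Ehhadh (0.98 ± 0.21) rose and 14 did not pass (adjusted p = 0.448 with an estimated correlation). Cyp4a14 read 10.23, 12.05 and 12.34 in wild-type males 1, 2 and 3, so the size of its rise leans on the first. Of 11 interferon response genes, Ifit1 (1.49 ± 0.38), Gbp3 (1.35 ± 0.17) and Ifit2 (1.06 ± 0.23) rose, with 8 higher when adjusted over the list alone (camera adjusted p = 0.233 with an estimated correlation). Of 15 xenobiotic response genes, Cyp2b10 (2.73 ± 0.51) and Nqo1 (1.34 ± 0.16) rose, and the adjusted p was 0.233 with an estimated correlation. Of 16 acute phase genes, Apcs (1.22 ± 0.21) and Itih4 (0.42 ± 0.10) rose (adjusted p = 0.501 with an estimated correlation). Of 14 gluconeogenesis and insulin response genes, Irs1 rose by 0.94 ± 0.23. No gene of the lipogenesis, cholesterol biosynthesis, proliferation or unfolded protein lists passed in knockout males, and Cyp7b1 was the one gene of 15 in the bile acid list that did.

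In knockout males some markers of other liver cells rose. Of 10 Kupffer cell markers, the complement subunits C1qa (0.87 ± 0.18) and C1qc (0.93 ± 0.24) and the receptor Vsig4 (0.85 ± 0.20) rose, and 9 were higher when adjusted over the list alone. The median over the list was 0.86, and the call of camera was lost with an estimated correlation (adjusted p = 0.233). Of 6 T and NK cell markers, Ccl5 (1.05 ± 0.17) and Gzma (0.63 ± 0.14) rose, with an adjusted p of 0.137 with an estimated correlation. Of 8 stellate cell markers, Col3a1 rose by 0.84 ± 0.19 (0.256 as adjusted p with an estimated correlation). None of the 8 endothelial, 5 B cell, 4 neutrophil, 5 cholangiocyte or 5 hepatocyte markers passed. Medians of the endothelial, B cell and hepatocyte lists were 0.28, 0.70 and 0.02, and the camera calls of the endothelial and B cell lists were lost with an estimated correlation (adjusted p = 0.233 and 0.161). The periportal and perivenous hepatocyte markers, 6 and 8 measured, did not pass. Alas2 (−2.70 ± 0.14) and Cela1 (−0.98 ± 0.18) fell, while the other 2 measured pancreas markers did not pass. The 1 measured marker each of adipose tissue and skeletal muscle did not pass.

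In all, limma called 500 genes in knockout males, 336 higher and 164 lower, of which 179 were also called in the same direction between wild-type females and males, 0 in the opposite direction and 321 not. With each array shifted to a common median the split was 283 and 236. The count was 233, 203 and 251 without knockout male 1, 2 or 3 and 250, 210 and 817 without wild-type male 1, 2 or 3 in turn. Without wild-type males 1 and 2 it was 99, with a single wild-type male left, which was assumed to vary like the other groups.

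In knockout females, Cyp3a16 rose by 4.71 ± 0.76 (adjusted p = 0.0115). It read 6.86, 4.85 and 9.16 in the 3 wild-type females, and the difference was 3.66 without wild-type female 2 and 5.81 without wild-type female 3. Its relative Cyp3a44 rose by 2.67 ± 0.30, the glucuronosyltransferase Ugt2b37 by 2.15 ± 0.49 and the enoyl-CoA isomerase Eci3 by 2.12 ± 0.39. The galectin Lgals9 (1.97 ± 0.34), the annexin Anxa6 (1.92 ± 0.30), Mlf2 (1.79 ± 0.26) and the corepressor Tle5 (1.71 ± 0.30) also rose. Cyp2b13 fell 19.2-fold (−4.26 ± 0.48, adjusted p = 0.0054). Slco1a1 (−3.90 ± 0.57), Serpina4-ps1 (−3.51 ± 0.75), Cyp2d9 (−3.04 ± 0.48), the NADPH oxidase Nox4 (−2.21 ± 0.26), the complement component C8a (−1.56 ± 0.22), Enpp3 (−1.46 ± 0.31) and Ociad2 (−1.33 ± 0.20) fell.

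Of the 18 male-biased list genes, Slco1a1, Cyp2d9 and Nudt7 (−0.55 ± 0.10) fell and 15 did not pass. The camera call of that list was lost with an estimated correlation (adjusted p = 0.923). Of the 24 female-biased list genes, Cyp3a16 and Cyp3a44 rose, Cyp2b13 fell and 21 did not pass, and over the list alone 8 were higher and 1 lower. Igfals rose by 1.01 ± 0.17 and was the 1 called gene of the growth hormone and IGF list. Igf1 (0.19 ± 0.12), Ghr (−0.33 ± 0.12) and Bcl6 (−0.93 ± 0.41) did not pass. The probe sets of Ghr disagreed: the other ones, at 12.25 and 8.04 on average, differed by 0.37 and −0.34. A dim probe set of Bcl6, at 4.87 on average, differed by 0.09, and by −0.56 in knockout males. Serpina6 differed by 0.79 ± 0.24 and did not pass (adjusted p = 0.107), though it did without wild-type female 3 (1.04). That setting left wild-type females 1 and 2, which had the highest 3′ to 5′ differences, as the only controls. Serpina6 read 12.91 in wild-type female 3 and 13.20 ± 0.12 (SD, n = 3) in knockout females. Hadha, of mitochondrial fatty acid oxidation, rose by 0.89 ± 0.16. The 16 cholesterol biosynthesis genes had a median of −0.51 with 0 past the threshold, and the camera call was lost with an estimated correlation (adjusted p = 0.923). None of the Kupffer cell, endothelial, stellate, T, B, neutrophil, cholangiocyte or hepatocyte markers passed, and the perivenous marker Rhbg rose by 0.79 ± 0.18.

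In all, limma called 362 genes in knockout females, 302 higher and 60 lower, and wild-type females 1 and 2, which the comparison uses as controls, had the highest 3′ to 5′ differences of the series. The count was 1 without those 2 arrays, with a single wild-type female left that was assumed to vary like the other groups, 0 with the 3′ to 5′ covariate (1416 genes at an unadjusted limma p under 0.05) and 0 when only the 6 female arrays were fitted (1632 genes at an unadjusted limma p under 0.05). All named changes in knockout females lost their calls in these 3 settings and kept their direction. The median change of the 302 genes called higher was 0.74 against wild-type females 1 and 2 and 0.68 against wild-type female 3. The 302 genes were picked with that female among the controls. Genes picked without it and without 1 knockout array had median changes of 0.77 to 0.90 in the picking arrays. In the arrays held out their median differences were 0.41 to 0.56. The split was 208 and 93 with each array shifted to a common median and 260 and 95 with quantile normalization repeated. Leaving out knockout female 1 or 2 gave 104 and 134 genes, leaving out wild-type female 1 or 2 gave 179 and 155, and leaving out knockout male 2 gave 237.

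The effect of the knockout differed between the sexes for 100 genes by the interaction test, 51 with a higher and 49 with a lower change in males. The changes of Cyp2b13 differed by 9.26 ± 0.68 (adjusted p = 1.36e-05), having risen in males and fallen in females. Sult3a1 (7.40 ± 0.48), Cyp2b9 (7.26 ± 0.36), Slc22a26 (7.04 ± 0.17), Hao2 (6.28 ± 0.34), Sult2a2 (5.65 ± 0.94), Slc22a27 (4.80 ± 0.30) and Rad51b (4.76 ± 0.70) changed more upward in males. Cyp4a12a (−6.65 ± 0.61), Ugt2b38 (−5.52 ± 0.57), Hsd3b5 (−5.36 ± 0.97), Nat8 (−4.47 ± 0.31), Scara5 (−4.36 ± 0.85), the complement gene C6 (−3.37 ± 0.33), Alas2 (−2.79 ± 0.20) and Cyp7b1 (−2.73 ± 0.16) changed more downward in males. Outside these, Mup10 differed by −2.58 ± 0.47 and Nqo1 by 1.19 ± 0.23.

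Of the fixed lists, 9 of 18 male-biased genes had a lower change and 13 of 24 female-biased genes a higher change in males, with 17 and 17 when adjusted over the list alone. Camera kept both calls with an estimated correlation (adjusted p = 0.0174 and 0.0116). Mup10 was the 1 called gene of the 3 urinary protein genes, Cyp7b1 of the 15 bile acid genes and Nqo1 of the 15 xenobiotic genes. The camera call of the urinary protein list was lost with an estimated correlation (adjusted p = 0.427). So were those of the cholesterol, acute phase, interferon and Kupffer cell lists, none of which held a called gene (adjusted p = 0.663, 0.628, 0.607 and 0.732). The changes of Slco1a1 and Cyp2d9, called in both sexes, did not differ detectably between the sexes (−2.60 ± 0.81 and −1.94 ± 0.68, adjusted p = 0.157 and 0.205), nor did those of Serpina6 (0.69 ± 0.34, adjusted p = 0.361), Bcl6 (−1.50 ± 0.58) or Elovl3 (−3.74 ± 0.94). The count of genes was 58 without knockout female 1, 52 and 43 without knockout male 1 or 2, and 52 without wild-type male 2. It was 167 with a clock covariate, 59 with the 3′ to 5′ covariate, and 55 and 43 without arrays 1 and 2 of the wild-type females or males, which leaves 1 array in that group.

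**Figure D3:**
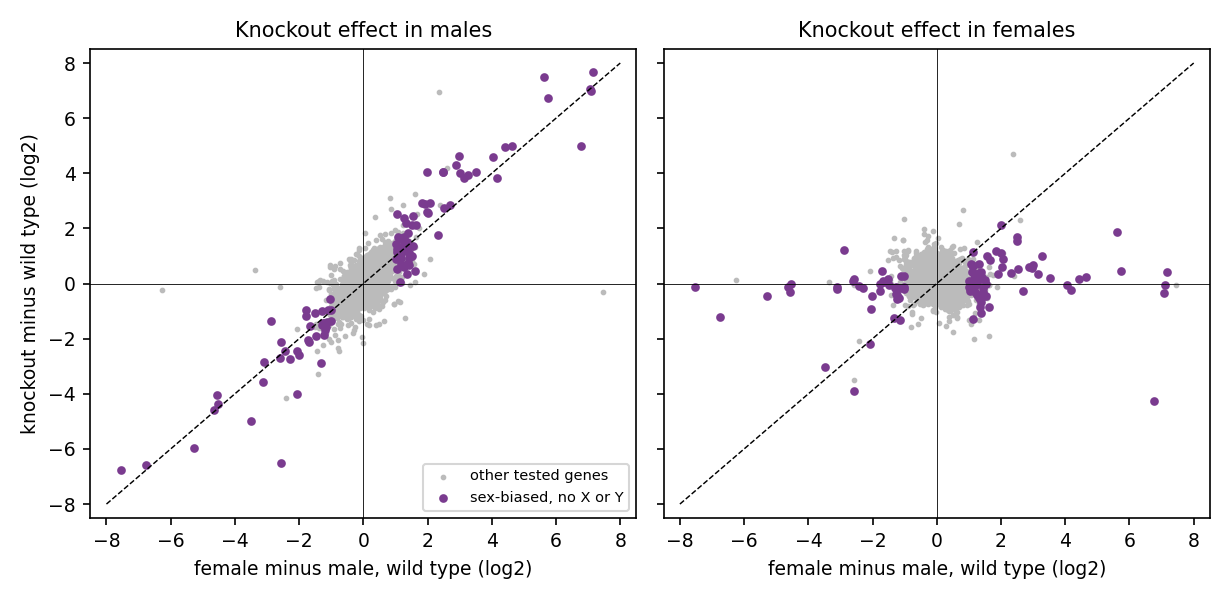
Knockout effect (log2) against the wild-type difference between females and males (log2) for the 12158 genes tested, in males on the left and in females on the right. Points are genes, those in purple being the 113 sex-biased genes outside the X- and Y-linked lists, and the dashed line marks equal values: the slope over these genes was 1.08 in males and 0.07 in females.

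The series asks what became of genes that differ between the sexes in wild type. There were 117 genes with a difference of at least 2-fold, 76 higher in females and 41 higher in males, and 113 of them were not on the lists of X- and Y-linked genes. All 113 had changed in the direction of the female level in knockout males, 102 of them past the threshold. Direction alone was counted, and a gene could pass the female level and end farther from it. Slco1a1 read 12.23 in wild-type males, 5.73 in knockout males and 9.66 in wild-type females. The list was chosen on wild-type arrays that also enter the knockout effect, so these counts are not independent evidence. By the interaction test the sex difference was smaller in the knockout for 51 of 117 genes, larger for 0, and not resolved for 66. The median absolute sex difference of the 113 genes was 1.50 in wild type and 0.24 in the knockout.

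**Figure D4:**
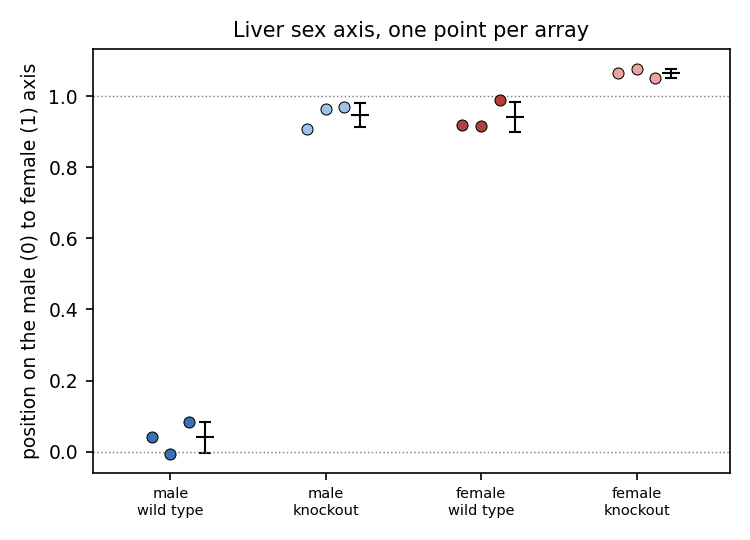
Position of each of the 12 arrays on an axis from the wild-type male mean (0) to the wild-type female mean (1), in units of that difference, over wild-type sex-biased genes, those of the X- and Y-linked lists included. Points are arrays and bars show the group mean ± SD (n = 3): knockout males averaged 0.948 ± 0.034 and wild-type females 0.942 ± 0.041. Outside the X- and Y-linked lists the mean of knockout males was 1.08.

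Placed on an axis from the wild-type male mean at 0 to the wild-type female mean at 1, knockout males averaged 0.948 ± 0.034 (SD, n = 3) and knockout females 1.06 ± 0.0135. This axis held all 117 sex-biased genes, those of the X- and Y-linked lists included. Wild-type arrays, each placed on an axis built without it, averaged 0.040 ± 0.044 for males and 0.942 ± 0.041 for females. Knockout males did not overlap wild-type males, and the exact two-sided permutation p of 0.10 (0.133 after Benjamini-Hochberg over 4 comparisons) was the smallest that 3 against 3 arrays allow. Knockout males and wild-type females could not be separated (difference 0.0053, exact permutation p = 1). Over the 113 genes outside the X- and Y-linked lists the mean position of knockout males was 1.08. The match with wild-type females therefore depends on the sex-linked genes. Knockout females lay above knockout males by 0.117 (exact permutation p = 0.10), and outside those lists this difference was −0.0024. Knockout females lay above wild-type females by 0.122 (exact permutation p = 0.10). In simulated data without a knockout effect, knockout males averaged 0.038, with a range of 0.015 to 0.058 over 20 draws. Knockout females averaged 0.968 there against 0.950 for wild-type females. The simulated noise was independent for each gene, without variation shared by the genes of an array. On an axis from the fixed lists the positions were 1.10 ± 0.05 for knockout males, 1.09 ± 0.05 for knockout females and 0.985 ± 0.090 for wild-type females. There knockout and wild-type females overlapped, with wild-type female 3 at 1.08 and knockout female 3 at 1.04.

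The wild-type sex difference and the knockout effect in males share the wild-type male arrays. Across 12158 genes, which are not independent replicates, their correlation was 0.762, against 0.502 for simulated groups without an effect. The covariance was 0.137 against a simulated 0.018. In both comparisons 113 genes were called higher and 66 lower, where independent lists of these sizes would share 4.50 and 1.11. Part of this excess may come from the shared arrays, since 3 control arrays are too few to be split. The wild-type sex difference and the knockout effect in females share the wild-type female arrays, with a correlation of −0.06 against a simulated −0.50 and a covariance of −0.0074 against −0.018. In these, 6 genes were called higher and 7 lower in both, against 4.05 and 0.405, and 7 were called in opposite directions.

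Between the knockout groups, Xist was higher in females (7.73 ± 0.13, adjusted p = 5.58e-12), and the Y-linked Eif2s3y (−5.91 ± 0.17), Kdm5d (−3.81 ± 0.16) and Uty (−2.51 ± 0.15) were lower. Erdr1 (2.04 ± 0.43), Anxa6 (1.66 ± 0.30), Mlf2 (1.48 ± 0.26), Ttc7b (1.46 ± 0.33), Ablim3 (1.35 ± 0.18), the extracellular superoxide dismutase Sod3 (1.29 ± 0.17) and Tfpt (1.27 ± 0.20) were higher in females. The other probe sets of Tfpt differed by 0.46, 0.43 and 0.10, from the brightest to the dimmest. Cyp2b13 was lower in knockout females than in knockout males (−2.50 ± 0.48, adjusted p = 0.0266), as were Tafa2 (−1.11 ± 0.20), Ociad2 (−0.91 ± 0.20), Rprd2 (−0.89 ± 0.20) and the gene model 1810014B01Rik (−0.78 ± 0.17). The difference of Rprd2 was 0.038 as the mean of its probe sets. Cyp2b9 (−0.10 ± 0.26), Hsd3b5 (−1.40 ± 0.68), Elovl3 (−0.82 ± 0.66) and Slco1a1 (0.03 ± 0.57) did not pass.

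Of the 113 sex-biased genes, 4 passed in the knockout: Ociad2 in the wild-type direction, and Cyp2b13, Tafa2 and Keg1 (0.78 ± 0.13) in the opposite one. Of all 234 calls between the knockout groups, 6 were kept without knockout male 1 and 6 without knockout male 2. Keg1 was the 1 called gene of the 18 on the fixed male-biased list and Cyp2b13 the 1 of 24 on the female-biased list. Hadha (0.90 ± 0.16), the stress-induced transcription factor Atf3 (0.91 ± 0.20) and the X-linked Eif2s3x (0.54 ± 0.10) were higher in females. For the X-linked list the camera adjusted p was 0.0766 with an estimated correlation. The lipogenesis and proliferation lists had medians of 0.44 and 0.52 with 0 genes past the threshold, and their camera calls were lost with an estimated correlation (both adjusted p = 0.649).

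In all, limma called 234 genes between the knockout groups, 225 higher and 9 lower in females, and 34 differed by at least 2-fold. The split was 79 and 9 with each array shifted to a common median and 11 and 3 when only the 6 knockout arrays were fitted. It was 3 and 3 without knockout male 1, the same without knockout male 2, 17 and 3 without knockout female 1, 147 and 8 without knockout female 3, and 138 and 7 without wild-type male 2.

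A common response of both sexes comprised 24 genes that rose and 11 that fell, where independent lists would share 8.35 and 0.809. Both calls use the same estimate of the spread of each gene, so these expected numbers may be too low. Cyp3a16 (6.93 in males and 4.71 in females), Cyp3a44 (3.09 and 2.67) and Eci3 (4.04 and 2.12) rose in both. Serpina4-ps1 (−6.54 and −3.51), Slco1a1 (−6.50 and −3.90), Cyp2d9 (−4.98 and −3.04) and Nox4 (−4.01 and −2.21) fell in both. Dct, which encodes dopachrome tautomerase of melanin synthesis, rose by 1.83 and 1.66 and differed by 0.04 between the sexes in wild type, and the interleukin receptor subunit Il1rap fell in both (−1.0 and −1.27). Igfals was in the common set as well. Cyp2b13 and Fnip2 (0.77 in males and −0.77 in females) were called in opposite directions. The effects in the 2 sexes use different arrays, and their correlation across genes was 0.280 against a simulated −0.0018.

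The common set was 0 genes with the 3′ to 5′ covariate and 0 without wild-type females 1 and 2, which leaves 1 array in that group, and its split was 17 and 18 with each array shifted to a common median and 16 and 18 with quantile normalization repeated. It was 18 and 14 without knockout female 1 or 2, 17 and 23 without wild-type female 1 or 2, 22 and 19 without knockout male 1 or 2, and 19 without wild-type male 2.

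Genes beside Sst were examined because a targeted locus can keep flanking DNA of the strain in which it was made. Of the 40 measured genes nearest to Sst, 20 on each side, 5 were called in knockout males (12.5% against 4.08% of the other genes, Fisher's exact p = 0.0232, 0.0463 after Benjamini-Hochberg over both sexes). These were Bcl6 (−2.44), Il1rap (−1.0), Ehhadh (0.98), Rtp4 and 1 unnamed gene model. Bcl6 is also on the fixed male-biased list and was lower in females in wild type (−2.06). For this gene an effect of the locus cannot be told apart from the fall of male-biased genes. In knockout females 2 were called, Il1rap (−1.27) and Fetub (5% against 2.97%, Fisher's exact p = 0.335). With 10 genes on each side the share was 20% in males and 10% in females (Fisher's exact p = 0.0081 and 0.118, 0.0162 and 0.118 after Benjamini-Hochberg). With 50 genes on each side the share was 7% in both sexes, with Fisher's exact p = 0.196 in males and 0.0296 in females (0.196 and 0.0591 after Benjamini-Hochberg).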

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

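The tests of mislabelled sex, of held-out knockout females and of the paralog Cyp2b9 were chosen after the result was seen, and the tests with the clock and 3′ to 5′ covariates use settings chosen after seeing the data. Groups of 3 arrays were too small for a test of single outlying arrays.

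The knockout effect differed between males and females by the interaction test for 100 genes. The difference in log2 was 9.26 for Cyp2b13, 7.40 for Sult3a1, 7.26 for Cyp2b9, 7.04 for Slc22a26, 6.28 for Hao2, 5.65 for Sult2a2, 4.80 for Slc22a27, 4.76 for Rad51b and 1.19 for Nqo1. It was −6.65 for Cyp4a12a, −5.52 for Ugt2b38, −5.36 for Hsd3b5, −4.47 for Nat8, −4.36 for Scara5, −3.37 for C6, −2.79 for Alas2, −2.73 for Cyp7b1 and −2.58 for Mup10. The medians of the fixed male-biased and female-biased lists were −2.53 and 2.17. Among 100 drawn splits of genotype within each sex, 6 gave as many interaction genes, the real one included (real 100, highest other 483), so chance could not be excluded at 0.05 by this count. For sex-biased genes with a reduced difference 6 of 100 splits also gave as many (real 51, highest other 147), and the same holds. The reduced count depends on which side of a split is named wild type, and each drawn split had a single naming. The number of splits with as many reduced genes is therefore not exact. In either case the 6 were among the 9 splits that keep the male genotypes apart, so these splits hold the knockout effect in males and are no picture of data without one. With mixed males the highest interaction count was 1. In simulated data without a knockout effect 0.1 sex-biased genes on average had a reduced difference (0 to 1 over 20 draws). Those draws used independent noise for each gene and held 225 sex-biased genes on average, where the data held 117. They lack variation shared by the genes of an array, so they do not decide on chance.

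For the contrasts of 3 against 3 arrays the 10 possible splits were too few for a share under 0.05. The real split was the 1 with as many genes in wild-type sex (245, highest other 0), knockout males (500, highest other 0), knockout females (362, highest other 1) and knockout sex (234, highest other 0). For the common response of both sexes 1 of 100 splits, the real one, gave as many genes (35, highest other 0). It was also the 1 drawn split that keeps the genotypes of both sexes apart, so this count does not test the overlap.

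Signal also appeared in probe sets outside the gene comparisons. Of 3327 tested probe sets that name no gene or several genes, 62 passed in knockout males, 43 higher and 19 lower.

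Knockout males lay at the female end of the sex axis. Their lowest Eif2s3y value, 9.32, exceeded the highest female value, 3.73, by 5.59, which argues against mislabelled sex. The slope of their knockout effect on the unadjusted wild-type sex difference was 1.07 with the clock covariate (1.05 to 1.09 over leave-one-out fits). It was 1.07 with the 3′ to 5′ covariate (1.06 to 1.09). The sex-biased genes were picked for a small spread within groups, so the clock slope had little room to fall. Wild-type male 3, with Per2 at 5.63 against 5.55 to 6.44 in knockout males, lay at 0.083 on the axis. That 1 array argues against clock phase at collection as the whole cause. The Gapdh 3′ to 5′ difference was 0.038 ± 0.108 (SD, n = 3) in wild-type and 0.015 ± 0.078 in knockout males. Such like values leave the covariate little to adjust and argue against RNA integrity as the whole cause of the male effect. A loss of sex-specific growth hormone signals after loss of somatostatin remains a possible explanation, as a hypothesis, since growth hormone was not measured here.

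More genes were higher than lower in knockout females, and genes picked as most raised without 1 knockout array and without wild-type female 3 differed from that female, in the array held out, by 0.582 of the change in the picking arrays (0.452 to 0.720), and 79.1% to 89.1% of them were higher there against 50.6% to 59.4% of all genes. Picking alone lowers such a share and 1 control array is too few to decide, so RNA integrity of wild-type females 1 and 2 stays open. With the 3′ to 5′ covariate the median change of the raised genes went from 0.73 to 0.69 and its median standard error from 0.14 to 0.17. The count of called genes went from 362 to 0. The median was 0.70 with the clock covariate (0.63 to 0.74). These genes were called for a small spread within groups, within which the clock genes varied widely. The clock covariate therefore had little room to move the median, and clock phase is not decided by it. An unlabelled batch of the knockout female arrays cannot be told apart from the knockout, and the 132 raised genes that were also higher than in knockout males do not decide it, since both comparisons use the same 3 knockout female arrays (correlation over all genes 0.532 against a simulated 0.502 without an effect), and a genotype effect specific to females stays open.

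Cyp2b13 was lower in knockout females and higher in knockout males than in wild type. Its relative Cyp2b9 differed by 0.43 in knockout females (95% interval −0.13 to 0.99), which argues against probes shared with that paralog as the source of the fall in females. In knockout males both genes rose, so shared probes could hold part of that rise. With Cyp2b9 at 12.12 in knockout males and 12.02 in knockout females, Cyp2b13 read 10.12 ± 0.85 and 7.62 ± 1.09 (SD, n = 3). This argues against shared probes as the whole source of the rise. Against wild-type female 3 alone, Cyp2b13 of the knockout females differed by −4.28 (−5.41 to −3.24), which argues against RNA integrity of the other 2 controls. A regulation of Cyp2b13 apart from that of Cyp2b9 is a possible explanation, as a hypothesis found on the same arrays.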

How the results depend on the processing

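The covariates and the settings that leave out 2 arrays together were chosen after seeing the data, and the other alternatives beforehand. Of 123 calls of named genes, 116 kept their direction and side of the threshold with the clock covariate, 115 with a common median, 113 without the filter, 104 with the replicate number as a block, 84 with the 3′ to 5′ covariate, 81 without wild-type males 1 and 2 and 76 without wild-type females 1 and 2. Of 105 such calls, 70 did without moderation and 63, the lowest share, in fits to the 6 arrays compared. Over all settings that leave out 1 array, 1215 of 1476 did and 0 reversed. The one reversal was Rprd2 between the knockout groups, 0.038 with the mean of all probe sets. Where a count moved below, the cause was not tested, except that a 2-fold or 4-fold minimum lowers counts by construction. Genes whose probe sets exceeded the array median, 4.94 to 4.97, on fewer than 3 arrays were not tested, which limits what can be said of dim genes.

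Leaving out 1 array gave 119 to 413 genes for wild-type sex, 203 to 817 for knockout males, 104 to 379 for knockout females, 6 to 266 for knockout sex, 43 to 140 for the interaction, 36 to 72 sex-biased genes with a reduced difference, 14 to 49 for the common response, and positions of 0.894 to 0.963 for knockout males and 1.02 to 1.07 for knockout females. The 3′ to 5′ covariate gave 114 for wild-type sex, 0 for knockout females (1416 at an unadjusted limma p under 0.05), 59 for the interaction and 0 for the common response, and the clock covariate 167 for the interaction. The next 2 settings leave 1 array in a wild-type group, assumed to vary like the other groups. Without wild-type females 1 and 2 the counts were 79 for wild-type sex, 1 for knockout females, 55 for the interaction and 0 for the common response. Without wild-type males 1 and 2 they were 63 for wild-type sex, 99 for knockout males, 238 for knockout females, 54 for knockout sex, 43 for the interaction and 17 for the common response. Array weights gave 1463 for knockout males, 222 for knockout females, 521 for knockout sex and 153 for the interaction. The model without moderation gave 160 for wild-type sex, 281 for knockout males, 237 for knockout females and 75 for knockout sex. Fits to the 6 arrays compared gave 116 for wild-type sex, 0 for knockout females (1632 at an unadjusted limma p under 0.05) and 14 for knockout sex. With a common median knockout sex gave 88.

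A 2-fold minimum left 117 genes for wild-type sex, 219 for knockout males, 69 for knockout females, 34 for knockout sex and 14 for the common response, and a 4-fold minimum 31 sex-biased genes with a reduced difference. On an axis from the fixed lists knockout males lay at 1.10 and knockout females at 1.09. Knockout males lay at 0.869 with every probe set on its own and at 1.0 with the mean of all probe sets. With an estimated correlation 10 of the 150 camera tests of a list in a contrast passed instead of 41. With 50 genes on each side of Sst 7% passed in knockout males and 7% in knockout females.

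The replicate number as a block gave 200 genes for wild-type sex, 389 for knockout males, 185 for knockout females, 112 for knockout sex, 66 for the interaction and 20 for the common response. The numbers do not pair the arrays: deviations of 18 same-number pairs correlated at −0.329 to 0.393 (median −0.0076), and 2 of 12 arrays correlated best with their own number.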

Other observations

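The list of terminal complement genes and its test were chosen after the result was seen on these same arrays, so the p-values below are not independent evidence. Complement proteins of the membrane attack complex are made in the liver, and 6 of 7 of their genes were tested. In knockout males 4 of them fell: C6 (−3.56 ± 0.23), C8b (−2.89), C8a (−2.33) and C9 (−1.66), with a median of −2.00 over the list (Fisher's exact p = 3.97e-05, 1.98e-04 after Benjamini-Hochberg over 5 contrasts, and camera adjusted p = 0.0259 with an estimated correlation). In knockout females C8a (−1.56), C8b (−1.26) and C9 (−0.82) fell, with a median of −0.51 (adjusted p = 0.107 with an estimated correlation). The calls of these genes in females were lost with the 3′ to 5′ covariate. C8a read 12.59 and 12.60 in wild-type females 1 and 2, 11.68 in wild-type female 3 and 10.73 ± 0.12 (SD, n = 3) in knockout females. In wild type 3 of the 6 were lower in females, with a median of −0.85 (adjusted p = 0.0259 with an estimated correlation). By the interaction test 2 genes passed (median −0.81, adjusted p = 0.0459 with an estimated correlation). Between the knockout groups limma called 0 of the 6 and the median was 0.06.

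The 3 probe sets of Cux2, a transcription factor gene known to be female-biased in liver, gave knockout differences in males of 0.07, 0.67 and 3.88 from the brightest to the dimmest, and wild-type sex differences of −0.02, 0.60 and 3.44. The named probe set was the brightest, and the others were not tested as genes.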
